A study of Oryza sativa with 12 samples.

How the data were processed

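Per the labels, rice cells in suspension were kept in Murashige and Skoog medium lacking sucrose for 12, 24 or 48 h, and control cells in the same medium with 3% sucrose for as long. A further 12 h set had control cells in 88 mM sorbitol. Polyadenylated RNA was isolated from total RNA, and starved cells were labelled with Cy5 and control cells with Cy3 on Agilent rice arrays, again per the labels. Each of the 12 samples was 1 array, and the labels gave 4 groups of 3 numbered replicates. No array had the dyes swapped.

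The values were the table of processed values that the authors deposited, with 21495 probes and 1 column per array. The deposited values were taken as natural log ratios of the channels of an array, from the values themselves. The lowest value of 2 columns was the natural log of a ratio of 0.01. In 12 h replicate 1, 312 values were logs of ratios with a single decimal on that scale (tolerance 1e-05) against 72 if they were log2 or log10. They were turned to log2. Column medians of log2 were -0.01, -0.01 and 0.11 for 12 h replicates 1 to 3, 0.00, 0.00 and 0.01 for sorbitol, 0.02, -0.03 and 0.01 for 24 h, and 0.02, -0.01 and 0.03 for 48 h. The scale was settled in this way only for columns with many ratios of a single decimal. On the natural log scale these numbered 0, 0 and 3 on the sorbitol arrays, 3 on 12 h replicate 3 and 0 on 24 h replicate 3. Those columns were taken to have the scale of the others. Centring, background correction and other normalization stayed unknown. Which channel was divided by which was not stated either, and Cy5 over Cy3 was taken from the dye labels. The software was not given in the sources used here. Scanner intensities were not used here, so signal over background was unknown for every probe.

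Blank cells made up 2.41% of the table and 13.6% of 48 h replicate 2. How blanks arose was not given in the sources used here. Nothing was filled in. A feature was tested in a comparison when every array of the groups compared had a value, so a gene with a blank on any array of a group had no test there. The SD of log2 ratios over probes was 0.90, 0.64 and 0.78 for 12 h replicates 1 to 3, 0.78, 0.98 and 0.65 for 24 h, 0.95, 1.26 and 0.65 for 48 h, and 0.30, 0.34 and 0.38 for sorbitol. Correlations between arrays of a group, across probes, which are not independent replicates, ran from 0.291 to 0.649 at 12 h, 0.356 to 0.692 at 24 h, 0.604 to 0.645 at 48 h and 0.701 to 0.795 for sorbitol.

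Probes were named through a table of GEO's annotation for the array, which gave 1 gene for 17839 probes, several for 21 and none for 3635. Gene IDs were looked up in a RefSeq gene table of the Japonica assembly ASM3414082v1, and 100% were found. No coordinates were used. Probes of 1 gene were averaged, which concerned 1859 genes with more than 1 probe, and other probes stayed separate without a name. This gave 19454 features, of which 15798 were genes, and 2111 of these had a name other than a locus or clone number.

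Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient for each of the 4 groups over all 12 arrays, so that all groups shared an estimate of the spread. The sorbitol arrays varied less than the others. With the shared spread, p-values against sorbitol are therefore likely too large and those against sucrose too small. Each group mean was tested against 0, and 4 differences between groups were tested: 24 minus 12 h, 48 minus 24 h, 48 minus 12 h, and 12 h against sucrose minus 12 h against sorbitol. The last is sorbitol over sucrose, and rests on starved cells of both sets being alike. All tests were two-sided, with Benjamini-Hochberg adjustment over the features of a comparison and a threshold of 0.05. No array was shared between groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

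Gene lists were tested with limma's camera on the moderated statistics, with a preset correlation of 0.01 between genes and again with an estimated correlation, where a list had at least 5 measured members. P-values were adjusted over the lists of a comparison. The 34 lists fixed at first matched words in gene descriptions. The gene table used held symbols and synonyms but no descriptions, and 6 of these lists reached 5 members. A second set of 46 lists by gene symbol, 43 of which reached 5 members, was therefore added after the gene names were seen and before values of single genes were looked at. Word lists and lists by symbol were adjusted separately.

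Genes were named by a rule. Among called genes with a name whose 3 arrays had the same sign (for differences, whose groups of 3 did not overlap), it took the 8 largest rises and 8 largest falls of each comparison and, from each list, the 2 members with the largest change. It also took a panel of 18 genes, of which 12 could be matched. The rule spoke of gene descriptions, and gene names were used in their place, with the lists by symbol in place of the word lists. The text leaves out many genes of the rule. The main fit, the word lists and this rule were fixed before the data were examined.

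The replicate numbers in the labels were checked for pairing. Deviations from the group means of same-numbered 24 and 48 h arrays correlated at 0.565, 0.442 and 0.494 over features. They were therefore taken to pair the arrays of these times. The fit set beforehand had no block and gave the main values, and values with the pairs as a block are given where they changed a call. The pairing rests on the numbers in the labels and on this check, since no label says what a number stands for.

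The fit was tested on simulated data for each comparison, over the features tested in it, with 200 of them changed. The noise was normal and independent between features, with the same SD in all groups, unlike the real arrays. Of features changed by a log2 of 1, it recovered 42%, 36%, 34% and 35% for 12, 24, 48 h and sorbitol, and 14%, 8%, 8% and 10% for 24 minus 12 h, 48 minus 24 h, 48 minus 12 h and sorbitol over sucrose. Of those changed by 2, it recovered 92%, 92%, 92% and 87%, and 62%, 64%, 66% and 68%. In a simulated 24 h comparison with 1 of 43 lists shifted by 1, camera called that list and no other. Since the simulated genes did not vary together, this cannot show how camera treats lists of correlated genes. Median standard errors per feature lay between 0.23 and 0.34 on the log2 scale.

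Alternatives covered median centring, scaling and quantile normalization of the arrays, single probes as features, other rules for missing values, a fit with only the arrays compared, array weights, a robust prior, a 2-fold threshold, an adjusted p under 0.01, the replicate number as a block, a filter on small ratios, and leaving out each array in turn, all set before the data were examined. Fits without the sorbitol arrays, without the arrays numbered 3, with the sorbitol ratios turned, or with pairs within the 24 and 48 h arrays were added afterwards. Scaling, centring and quantile normalization moved the median of all features by less than 0.1.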

Results

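Rice (Oryza sativa) cells growing in suspension culture were deprived of sucrose, and their messenger RNA was compared with that of fed cells on Agilent rice oligonucleotide arrays. Each of the 12 arrays carried RNA from cells kept without sucrose, labelled with Cy5, beside RNA from control cells, labelled with Cy3. The arrays formed 4 groups of 3: 12, 24 and 48 h without sucrose against control cells in 3% sucrose, and 12 h without sucrose against cells in 88 mM sorbitol. Sorbitol served as the osmotic control in the design text. The fit held 19454 features, of which 15798 were genes and 3656 were probes without a gene in the table used here. The number of arrays limited the precision. The labels did not say whether the 3 arrays of a group came from separate cultures, so p-values measured only the spread between arrays, which may be technical.

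All values are log2 ratios of cells without sucrose over control cells, as the mean ± SD of 3 arrays (n = 3), and adjusted p-values came from limma. The deposited values did not state which channel was divided by which. For the arrays against sucrose the direction is the likely one, since the labels gave Cy5 to the starved cells and the starvation-induced amylase genes RAmy3D and RAmy3E had positive ratios. For the arrays against sorbitol it rests on the dye labels alone, and every sign given against sorbitol holds only if those ratios ran the same way. Every array had the same dye orientation, so dye bias of a probe stayed in each mean ratio. It cancelled only in differences between groups, and there only where it was of equal size on the arrays.

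After 12 h, the comparison asked which genes responded first to the loss of sucrose. The sugar transporter gene SWEET1B (LOC4338851) had a log2 ratio of 3.95 ± 0.72, a 15.5-fold rise, and the starch-degrading alpha-amylase gene RAmy3E (LOC4345812) one of 2.93 ± 1.06. The hexokinase gene HXK6 (LOC4338010) rose by 2.98 ± 0.46. RAmy3D (LOC4345814) also rose, by 2.34 ± 1.36, although its 2 probes gave 0.64 and 4.04. The sucrose synthase gene SUS1 (LOC4333062), whose enzyme cleaves sucrose, had a ratio of -2.05 ± 0.84. The lists these genes belong to did not pass at 12 h. Of 14 sugar transport genes 5 rose and 2 fell, also when adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.0729). Of 8 starch breakdown genes 2 rose, also when adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.0644).

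All 6 measured genes of the list of leucine breakdown and of the electron transfer flavoprotein, which passes electrons from amino acid breakdown to the respiratory chain, rose at 12 h. All 6 also rose when adjusted over the list alone. Their median log2 ratio was 1.66, and the limma camera test against all other genes gave an adjusted p = 1.98e-07 (adjusted p = 0.066 with an estimated correlation). Among them was the isovaleryl-CoA dehydrogenase gene IVD (LOC4337676, 2.78 ± 0.55). The list also held the D-2-hydroxyglutarate dehydrogenase gene D2HGDH (2.10 ± 1.14), whose enzyme is part of neither leucine breakdown nor the flavoprotein itself. GDH2 (LOC4336554), which encodes a glutamate dehydrogenase, rose by 2.63 ± 0.55, with 1.44 and 3.83 on its 2 probes. PPDKB (LOC4338750), encoding a pyruvate, phosphate dikinase, rose by 3.80 ± 0.88.

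Of 6 measured dehydrin and late embryogenesis abundant protein genes, which are known from drying seeds and water stress, 2 rose at 12 h, and 4 rose when adjusted over the list alone. Their median was 1.57 (camera adjusted p = 0.00512, and adjusted p = 0.372 with an estimated correlation), and RAB16B (LOC4350453) reached 2.92 ± 0.50. The tonoplast aquaporin gene TIP3;1 (LOC4348981) rose by 2.77 ± 0.43, the transcription factor gene WRKY62 (LOC4347070) by 3.12 ± 0.52, the SnRK2-type kinase gene SAPK6 by 1.98 ± 0.54, and the SnRK1-type kinase gene OSK3 by 1.97 ± 0.27.

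Genes of DNA replication shifted downward at 12 h, with a median of -0.58 over 24 genes (camera adjusted p = 0.0025, and adjusted p = 0.558 with an estimated correlation). Of these genes 4 fell, and 8 fell and 1 rose when adjusted over the list alone. All 3 measured genes of fermentation fell, also when adjusted over the list alone. They included the pyruvate decarboxylase gene PDC1 (LOC4339066; -2.66 ± 0.92), and this list was too small for the camera test. The largest fall of a called gene with a name was that of CCR1 (LOC4331085; -3.19 ± 1.32), a cinnamoyl-CoA reductase gene of lignin synthesis. The kinase gene CIPK16 (LOC4347071; -3.01 ± 1.05) and the auxin response repressor gene IAA1 (-1.90 ± 0.60) also fell.

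The glycolysis list (9 genes, 2 fell, 4 when adjusted over the list alone) had a median of -0.57 and the ribosomal protein list (17 genes, 2 fell, 4 when adjusted over the list alone) one of -0.55. Their camera adjusted p-values were 0.00512 and 0.00183. With an estimated correlation they were adjusted p = 0.454 and adjusted p = 0.558, and without 12 h replicate 1 they were 0.133 and 0.0624. GAPC2 (LOC4336216), encoding a cytosolic glyceraldehyde-3-phosphate dehydrogenase, had a ratio of -1.92 ± 0.59, and the ribosomal protein gene RPS10-1 one of -1.47 ± 0.36. The 13 genes of pyruvate dehydrogenase and the tricarboxylic acid cycle did not pass at 12, 24 or 48 h, with list medians of 0.06, -0.06 and -0.22 (adjusted p = 0.877, 0.984 and 0.533). Seed storage protein genes, markers of another cell type, had medians of 0.11, -0.01 and 0.02 over 6 genes at 12, 24 and 48 h (adjusted p = 0.601, 0.909 and 0.926).

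More lists passed at 12 h. Auxin response genes had a median of -0.34, with 8 of 40 fallen and 1 risen, and 9 fallen and 1 risen when adjusted over the list alone. Cyclins and their kinases had one of -0.44, with 4 of 19 fallen, also when adjusted over the list alone. Kinesins had one of -0.44, with none of 24 called either way. NAC and WRKY transcription factors had one of 0.48, with 4 of 13 risen, also when adjusted over the list alone. Camera adjusted p-values were 0.00283, 0.0171, 0.0131 and 0.0212. These were adjusted p = 0.251, 0.612, 0.558 and 0.483 with an estimated correlation. All but the kinesin call were lost without 12 h replicate 2, and all but the auxin call without 12 h replicate 1, with adjusted p up to 0.0533, 0.108, 0.154 and 0.133.

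At 12 h, limma called 1660 of 18270 tested features at an adjusted p under 0.05, 921 higher and 739 lower, of which 1057 changed at least 2-fold. All 3 arrays had the same sign for 40.2% of features, where chance gives 25% for independent arrays centred on 0. Probe dye bias common to the arrays would raise this share, so 25% is no strict measure here. The count was 382 without 12 h replicate 1, 1072 without 12 h replicate 2, and 1091, 1077 and 1105 without sorbitol replicate 1, 2 or 3, which enter through the shared spread. It was 815 when only the 12 h arrays entered the fit, 599 when the sorbitol arrays were left out, and 2760 without the arrays numbered 3 (1327 higher and 1433 lower). Of 233 called genes with a name, the naming rule took 69. Of these 69, 24 kept the call without any single array and 47 when only the 12 h arrays were fitted. The genes named in the paragraphs on 12, 24 and 48 h as risen or fallen were chosen from those that kept it.

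**Figure D1:**
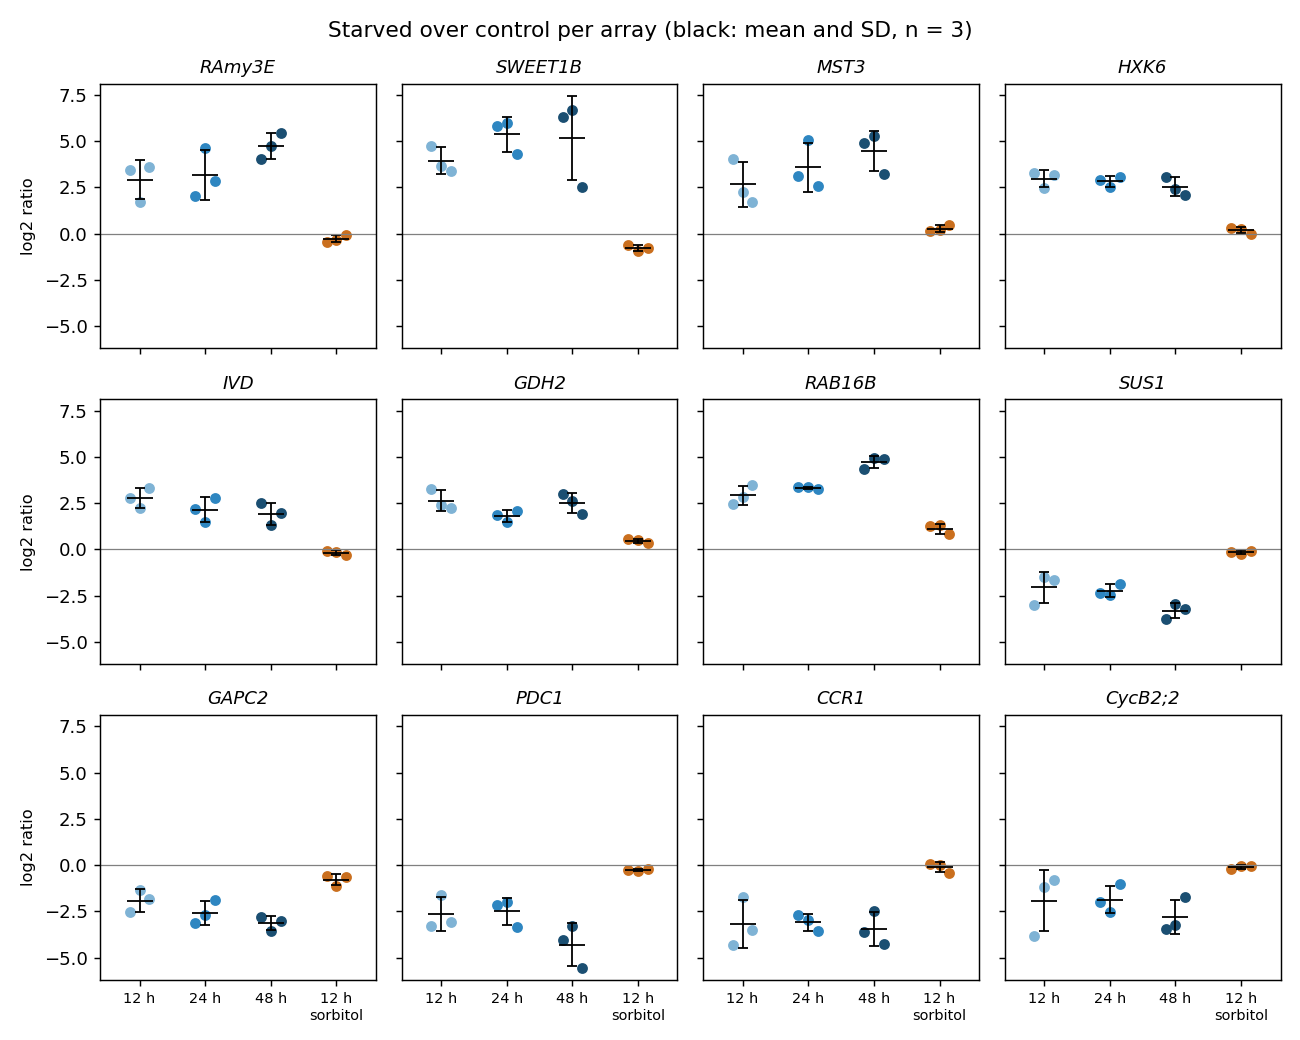
Log2 ratio of cells without sucrose over control cells on each array, for 12 genes, at 12, 24 and 48 h against sucrose and at 12 h against sorbitol. Black marks show the mean and SD of 3 arrays. RAmy3E averaged 2.93, 3.17 and 4.74 against sucrose and -0.28 against sorbitol.

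After 24 h, the second time point, SWEET1B averaged 5.37 ± 0.94, a 41.4-fold rise, and the monosaccharide transporter gene MST3 (LOC4342198) averaged 3.59 ± 1.32. RAmy3E rose by 3.17 ± 1.33 and HXK6 by 2.83 ± 0.29. Of 14 measured sugar transport genes, 5 rose and 2 fell, with the same counts adjusted over the list alone. Their median was 0.29 (camera adjusted p = 0.0119, and adjusted p = 0.243 with an estimated correlation). Of 8 starch breakdown genes, 2 rose, also when adjusted over the list alone, with a median of 0.86 (camera adjusted p = 0.0208, and adjusted p = 0.219 with an estimated correlation). The cleavage gene SUS1 had a ratio of -2.23 ± 0.34.

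Genes of the leucine breakdown and flavoprotein list stood higher at 24 h as well, with 5 of 6 risen and 6 when adjusted over the list alone. Their median was 1.13 (camera adjusted p = 4.07e-05, and adjusted p = 0.187 with an estimated correlation), with IVD at 2.14 ± 0.66 and D2HGDH at 1.94 ± 0.21. Of 6 dehydrin genes 2 rose, and 4 when adjusted over the list alone, with a median of 1.66 (camera adjusted p = 0.00118, and adjusted p = 0.219 with an estimated correlation). RAB16B averaged 3.34 ± 0.06 and rab25 (LOC4326935) 2.97 ± 0.37. Of 7 metallothionein genes 3 rose, and 4 when adjusted over the list alone, with a median of 0.92 (camera adjusted p = 0.00995, and adjusted p = 0.219 with an estimated correlation). The chitinase gene Cht-3 (LOC4342114) rose by 3.35 ± 1.33 and the catalase gene CAT-B (LOC4342124) by 1.59 ± 0.42. Among the lists made from words in gene names, pathogenesis-related proteins passed at 24 h, with 4 of 7 risen, also when adjusted over the list alone, and a median of 1.70. The camera adjusted p was 0.00449 (adjusted p = 0.0344 with an estimated correlation).

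Genes of growth and division shifted downward at 24 h. DNA replication genes had a median of -0.60 (5 of 24 fell, 10 when adjusted over the list alone), kinesins, the motors of the spindle and other microtubules, one of -0.80 (2 of 24 fell, 14 when adjusted over the list alone), cyclins and their kinases one of -0.49 (4 of 19 fell, 7 when adjusted over the list alone), and ribosomal proteins one of -0.47 (3 of 17 fell, 3 when adjusted over the list alone). Camera adjusted p-values were 0.000377, 0.000579, 0.00278 and 0.00199. With an estimated correlation they were adjusted p = 0.446, 0.361, 0.595 and 0.595. Among 40 auxin response genes, 10 fell, and 14 fell and 2 rose when adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.000579, and adjusted p = 0.219 with an estimated correlation). IAA9 averaged -1.92 ± 0.68.

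Glycolysis genes had a median of -0.78 at 24 h, with 4 of 9 fallen and 6 when adjusted over the list alone (camera adjusted p = 0.000579, and adjusted p = 0.327 with an estimated correlation). GAPC2 averaged -2.57 ± 0.66. Of 4 fermentation genes 3 fell, also when adjusted over the list alone, among them PDC1 (-2.51 ± 0.74) and PDC2 (LOC4332519; -1.91 ± 0.08). The lignin synthesis genes CAD7 (LOC4336968), a cinnamyl alcohol dehydrogenase, and CCR1 fell, with ratios of -3.45 ± 1.14 and -3.08 ± 0.46.

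Further lists shifted upward at 24 h. Cystatins had a median of 0.86, with 3 of 8 risen and 4 when adjusted over the list alone. Chitinases and related proteins had one of 0.45, with 5 of 15 risen, also when adjusted over the list alone. NAC and WRKY factors had one of 0.75, with 4 of 12 risen and 5 when adjusted over the list alone. JAZ proteins had one of 0.50, with 1 of 12 risen, also when adjusted over the list alone. Camera adjusted p-values were 0.00798, 0.0145, 0.0387 and 0.0461. These were adjusted p = 0.361, 0.243, 0.433 and 0.676 with an estimated correlation. All were lost without 24 h replicate 2, those of chitinases and JAZ proteins also without 24 h replicate 3, and that of NAC and WRKY factors also without 24 h replicate 1. The NAC and WRKY call was also lost without 12 h replicate 3, and the JAZ call without 12 h replicate 1 or 3 or 48 h replicate 3. Adjusted p rose up to 0.196, 0.0588, 0.329 and 0.793. With a single array left out, the medians fell as low as 0.49, 0.33, 0.39 and 0.08. Scaling ended the last 2 calls (adjusted p = 0.0529 for each), as did quantile normalization (0.0501 and 0.0652). Without the arrays numbered 3 the chitinase and JAZ calls ended (0.0544 and 0.12), and with only the 24 h arrays the JAZ call (0.0521).

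At 24 h, limma called 1634 of 19003 tested features, 899 higher and 735 lower, of which 1170 changed at least 2-fold. All 3 arrays had the same sign for 42% of features. The count was 670, 515 and 2641 without 24 h replicate 1, 2 or 3 (1287 higher and 1354 lower for the last), and 1084, 1081 and 1088 without sorbitol replicate 1, 2 or 3. It was 368 when only the 24 h arrays were fitted, 679 without the sorbitol arrays, 6283 with array weights (2958 higher and 3325 lower) and 3944 without the arrays numbered 3 (1742 higher and 2202 lower). Of 239 called genes with a name, the naming rule took 69. Of these 69, 30 kept the call without any single array, and 30 when only the 24 h arrays were fitted.

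After 48 h, the last time point, SWEET1B averaged 5.18 ± 2.29, RAmy3E 4.74 ± 0.70, a 26.6-fold rise, MST3 4.47 ± 1.08 and HXK6 2.53 ± 0.52. RAmy3D rose by 2.62 ± 0.57, with 0.37 and 4.88 on its 2 probes. The amylase gene RAmy3A, by contrast, had a ratio of 2.12 ± 2.69 and did not pass (adjusted p = 0.0643). SUS1 fell by 3.31 on the log2 scale (SD 0.42). Cht-3 averaged 5.47 ± 1.38, a 44.3-fold rise, the metallothionein gene MT1B (LOC4332487) 4.82 ± 1.69, and RAB16B 4.73 ± 0.32.

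Glycolysis genes fell nearly as a group at 48 h. Of 9 measured, 8 fell, also when adjusted over the list alone, with a median of -2.12 (camera adjusted p = 5.95e-06, and adjusted p = 0.205 with an estimated correlation). GAPC2 averaged -3.12 ± 0.40 and the enolase gene Eno1 (LOC4348176) -2.97 ± 0.94. All 3 measured fermentation genes fell, also when adjusted over the list alone, with PDC1 at -4.30 ± 1.14 and PDC2 at -2.70 ± 0.54.

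Of 17 ribosomal protein genes, 12 fell at 48 h, and 15 when adjusted over the list alone, with a median of -1.0 (camera adjusted p = 5.95e-06, and adjusted p = 0.495 with an estimated correlation). RPL5 averaged -1.95 ± 0.52 and RPS10 -1.61 ± 0.65. DNA replication genes had a median of -0.91, with 12 of 22 fallen and 14 when adjusted over the list alone (camera adjusted p = 1.17e-05, and adjusted p = 0.532 with an estimated correlation). PCNA, encoding the sliding clamp of DNA polymerase, averaged -1.56 ± 0.45 and the replication protein A gene RPA70b -2.77 ± 1.34. Cyclins and their kinases had a median of -0.79, with 7 of 17 fallen and 10 when adjusted over the list alone (camera adjusted p = 0.000399, and adjusted p = 0.564 with an estimated correlation). The mitotic cyclin gene CycB2;2 (LOC4342121) averaged -2.80 ± 0.93. Of 38 auxin response genes 17 fell and 1 rose, and 17 fell and 2 rose when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.0053, and adjusted p = 0.205 with an estimated correlation).

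Genes of the leucine breakdown and flavoprotein list kept a positive shift at 48 h, with 5 of 6 risen, 6 when adjusted over the list alone, and a median of 1.15 (camera adjusted p = 0.000877, and adjusted p = 0.205 with an estimated correlation). Of 6 dehydrin genes 4 rose, also when adjusted over the list alone, with a median of 2.11 (camera adjusted p = 0.0014, and adjusted p = 0.205 with an estimated correlation). Of 7 metallothionein genes 4 rose, also when adjusted over the list alone, with a median of 1.78 (camera adjusted p = 0.00331, and adjusted p = 0.205 with an estimated correlation). The oryzacystatin gene OC-I, a cysteine protease inhibitor, averaged 2.85 ± 1.36 and CAT-B 2.62 ± 0.64. Sugar transport genes had a median of 0.81, with 5 of 12 risen and 2 fallen, and 7 risen and 2 fallen when adjusted over the list alone. Chitinases and related proteins had one of 1.34, with 6 of 12 risen, also when adjusted over the list alone. Their camera adjusted p-values were 0.0214 and 0.0134. With an estimated correlation they were adjusted p = 0.325 and adjusted p = 0.372, and without 48 h replicate 2 they were 0.102 and 0.116. With a single array left out, the 2 medians fell as low as 0.20 and 0.18. The list of pathogenesis-related proteins made from words had a median of 2.01, with 4 of 6 risen, also when adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.0856 with an estimated correlation). Without 48 h replicate 2 its adjusted p was 0.116, and without the arrays numbered 3 it was 0.0665.

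Cystatins had a median of 1.23 at 48 h, with 5 of 7 risen and 1 fallen, NAC and WRKY factors one of 0.87, with 4 of 12 risen and 5 when adjusted over the list alone, and JAZ proteins one of 0.72, with 4 of 11 risen and 5 when adjusted over the list alone. The cystatin counts were the same over the list alone. Kinesins had a median of -0.61, with 7 of 22 fallen and 1 risen, and 9 fallen and 1 risen when adjusted over the list alone. Camera adjusted p-values were 0.0214, 0.0214, 0.0149 and 0.0214. With an estimated correlation they were adjusted p = 0.584, 0.495, 0.612 and 0.612. The first 3 calls were lost without 48 h replicate 2 (adjusted p = 0.0616, 0.137 and 0.179) and the kinesin call without 48 h replicate 1 (0.197). Without the arrays numbered 3 the cystatin call ended (adjusted p = 0.093).

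At 48 h, limma called 4307 of 16916 tested features, 2106 higher and 2201 lower, of which 2627 changed at least 2-fold. All 3 arrays had the same sign for 54% of features. The count was 2787 without 48 h replicate 1 and 1503 without 48 h replicate 2 (786 higher and 717 lower). It was 890 when only the 48 h arrays were fitted, 2600 without the sorbitol arrays, and 2700 with array weights. Of 614 called genes with a name, the naming rule took 88. Of these 88, 58 kept the call without any single array and 60 when only the 48 h arrays were fitted.

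**Figure D2:**
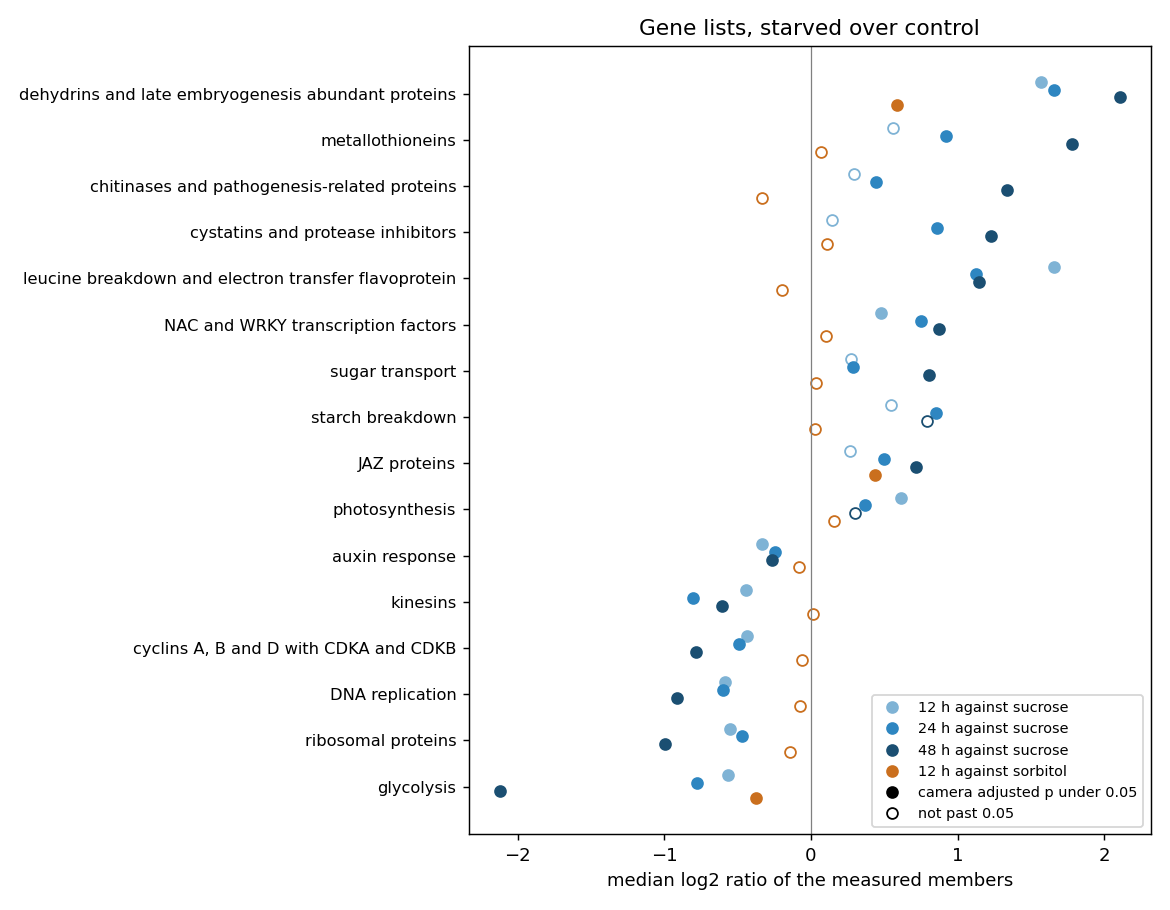
Median log2 ratio of 16 gene lists at 12, 24 and 48 h against sucrose and at 12 h against sorbitol. Filled marks passed the camera test with the preset correlation, and open marks did not. The glycolysis median was -0.57, -0.78 and -2.12 against sucrose and -0.37 against sorbitol.

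Across the 3 time points, 456 features rose and 375 fell at all 3 times among 16803 tested at each, and 4 were called in opposite directions at different times. Among those that rose each time were SWEET1B, RAmy3E, HXK6, RAB16B, IVD and GDH2. SUS1, PDC1, GAPC2, CCR1 and CIPK16 fell each time. Between 12 and 24 h, 496 rises and 394 falls were shared, where independent lists of those sizes would share 44.9 and 29.7. The time points shared no array, but probe dye bias common to all arrays may have added to the overlap. The tests also shared an estimate of the spread per feature, and the arrays numbered 3 deviated together. Independent lists are therefore no strict measure here. The number shared by all 3 times, 831, was 311 without 12 h replicate 1, 462 and 421 without 24 h replicate 1 or 2, 361 without the sorbitol arrays, 225 when each time was fitted alone, and 1532 without the arrays numbered 3 (657 higher and 875 lower).

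Differences between the times were tested directly. For SUS1, 48 h lay below 24 h by a log2 difference of -1.08 (SE 0.38, adjusted p = 0.999) and below 12 h by one of -1.26 (SE 0.38, adjusted p = 0.345). RAmy3E at 48 h exceeded 24 h by 1.56 (SE 0.64, adjusted p = 0.999) and 12 h by 1.81 (SE 0.64, adjusted p = 0.393). Neither gene passed. With the pairs of 24 and 48 h arrays as a block, RAmy3E (SE 0.43, adjusted p = 0.683) and SUS1 (SE 0.32, adjusted p = 0.726) did not pass either, though all 3 pairs had the same sign for each. Comparing 24 h with 12 h, limma called 0 of 18178 features (695 at an unadjusted p under 0.05), and every other fit tried also called 0. Comparing 48 h with 24 h, it called 0 of 16889 features (487 at an unadjusted p under 0.05). The arrays of these times with the same number deviated together, and a fit of the 24 and 48 h arrays alone with the replicate number as a block called 1 gene (967 features at an unadjusted p under 0.05), LOC4329468, while every other fit tried called 0. Its mean was 3.02 at 24 h and 0.10 at 48 h (log2 difference -2.92, SE 0.31, adjusted p = 0.0396), and it was named after its values were seen.

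Comparing 48 h with 12 h, limma called 1 of 16824 features (1676 at an unadjusted p under 0.05). This gene without a name, LOC4332932, also named after its values were seen, averaged 2.00 at 12 h and -0.78 at 48 h (log2 difference -2.78, SE 0.34, adjusted p = 0.0343). The count was 0 without 12 h replicate 1 or 2, any sorbitol replicate, 24 h replicate 1, or 48 h replicate 1 or 3. It was 23 without 24 h replicate 2, 2 without 24 h replicate 3, and 0 when only the arrays of these times were fitted or the sorbitol arrays were left out. Without 48 h replicate 2 and with quantile normalization 1 feature was called, but it was not LOC4332932, whose adjusted p was 0.0925 and 0.0634. Over all alternatives its adjusted p ran from 0.013 to 0.367. The groups of 3 did not overlap for 5.86%, 4.86% and 11.1% of features in the 3 comparisons of times, in order. The 10% that chance gives with exchangeable arrays is no measure for these, since arrays of different times deviated together. This held for same-numbered arrays of 24 and 48 h. Of the 12 h arrays, only replicate 3 deviated together with its own number at the other times.

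Some gene lists differed between times with the preset correlation, but none passed with an estimated correlation. From 24 to 48 h the glycolysis list shifted downward, with a median difference of -0.84 (camera adjusted p = 4.76e-06, and adjusted p = 0.613 with an estimated correlation). From 12 to 48 h it shifted by -1.32 (camera adjusted p = 1.16e-05, and adjusted p = 0.347 with an estimated correlation), and no member fell over all genes while 5 did adjusted over the list alone. Metallothioneins shifted upward from 12 to 48 h by 0.99 (camera adjusted p = 0.00107, and adjusted p = 0.273 with an estimated correlation), with 4 members risen adjusted over the list alone. These shifts passed without any single array, though the first median weakened to as little as -0.41. The first also had an adjusted p of 0.103 when the arrays numbered 3 were left out. Dehydrins differed between 24 and 48 h by a median of 0.43 (camera adjusted p = 0.0483, and adjusted p = 0.704 with an estimated correlation). With the replicate number as a block over all arrays the adjusted p was 0.0534. A block of pairs within the 24 and 48 h arrays kept the call (camera adjusted p = 0.0301). Without 24 h replicate 3, 48 h replicate 2 or 48 h replicate 3 the adjusted p was as high as 0.714. Without 48 h replicate 2 the sign of this median turned, to -0.14. With the pairs as a block within the 24 and 48 h arrays, DNA replication and JAZ genes passed as well, downward and upward (adjusted p = 0.0143 for each), where without it their adjusted p-values were 0.0858 and 0.17 (adjusted p = 0.964 for each with an estimated correlation).

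Against sorbitol, both cultures lacked sucrose, and the 12 h comparison asked which genes differed when the control medium held 88 mM sorbitol as an osmotic substitute. Ratios were small. Several genes with large changes against sucrose lay near 0, with RAmy3E at -0.28 ± 0.19 (adjusted p = 0.965), RAmy3D at 0.03 ± 0.03 (adjusted p = 0.996) and SUS1 at -0.15 ± 0.10 (adjusted p = 0.974). Others lay further off, with SWEET1B (LOC4338851) at -0.78 ± 0.16 (adjusted p = 0.908) and RAB16B (LOC4350453) at 1.12 ± 0.26 (adjusted p = 0.116). These p-values came from the spread shared by all groups, not from the SD given beside them. Over the 1660 features called at 12 h against sucrose, the median absolute log2 ratio was 1.16 against sucrose and 0.22 against sorbitol, and 40 of them were at least 2-fold apart from sorbitol. Of the 69 genes that the naming rule took from them, 64 had an absolute log2 ratio under 1 against sorbitol.

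Dehydrin genes stood higher in cells without sucrose than in cells in sorbitol. Their median was 0.59 over 6 genes (camera adjusted p = 0.000293, and adjusted p = 0.372 with an estimated correlation), and none rose over all genes while 3 did adjusted over the list alone. The genes of JAZ proteins, repressors of jasmonate signalling, had a median of 0.44 over 12 genes, with 1 risen, also adjusted over the list alone (camera adjusted p = 0.00262, and adjusted p = 0.764 with an estimated correlation). That gene was JAZ13 (LOC4348531), at 1.62 ± 0.38. The glycolysis list passed downward, with a median of -0.37 over 9 genes, none of them called over all genes or over the list alone (camera adjusted p = 0.0413, and adjusted p = 0.764 with an estimated correlation). That call was lost without sorbitol replicate 2, 24 h replicate 2 or 48 h replicate 2 (adjusted p up to 0.0986) and after scaling (adjusted p = 0.0909). The protein phosphatase gene PP2C59 (LOC4341949) averaged 1.64 ± 0.30 and ELA3 (LOC4341858) 1.45 ± 0.31. None of these 3 named genes kept the call without every single array in turn. The largest rise was that of LOC4333949, a gene without a name chosen after its values were seen, at 2.84 (adjusted p = 0.00749).

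Against sorbitol, limma called 10 of 19435 features, all 10 higher (or lower, if the ratio ran the other way, with 1262 at an unadjusted p under 0.05), and all 3 arrays had the same sign for 62.8% of features. The count was 0 without any 1 of the 3 sorbitol replicates or without the arrays numbered 3, 2 without 24 h replicate 1, 6 without 48 h replicate 3 and 22 without 48 h replicate 2. The shared spread was wider than that of the sorbitol arrays. With the arrays centred and scaled, 2815 features passed (1341 higher and 1474 lower), with quantile normalization 3871 (1921 higher and 1950 lower), and with array weights 7955. Scaling and quantile normalization give all arrays a like spread, and so widen the sorbitol ratios by construction. With only the sorbitol arrays fitted, 6979 passed (3553 higher and 3426 lower), with a median absolute log2 ratio of 0.37, and 153 of these were at least 2-fold.

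**Figure D3:**
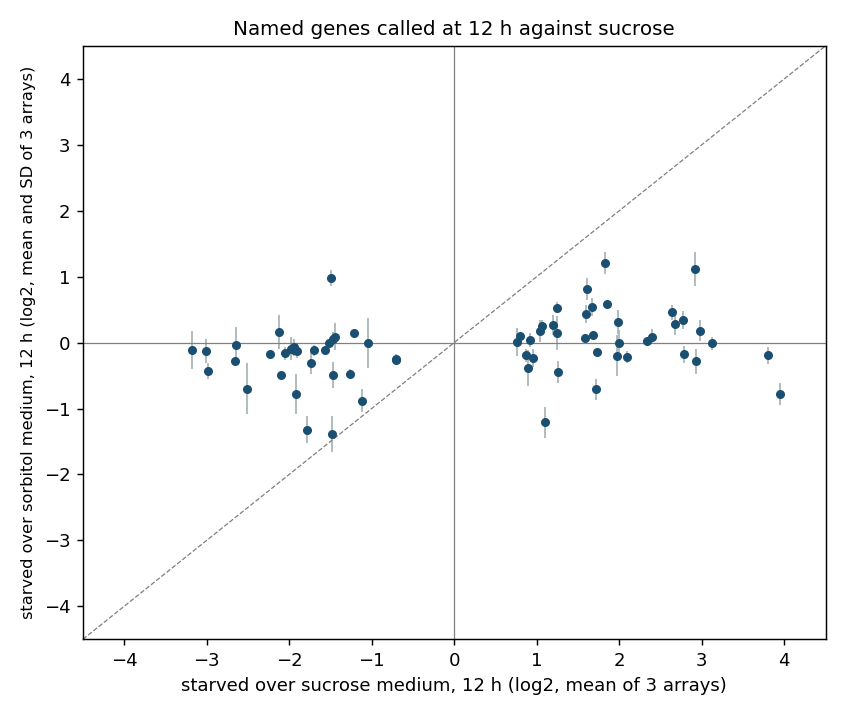
Mean log2 ratio of the 69 genes that the naming rule took from those called at 12 h. Ratios against sucrose are on the horizontal axis and those against sorbitol, with the SD of 3 arrays, on the vertical axis. The dashed line marks equality. Most genes lie near 0 on the vertical axis, and 64 of the 69 have an absolute log2 ratio under 1 there.

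The difference between the 2 sets of 12 h ratios set cells in sorbitol against cells in sucrose, with the starved cells as the common partner and both ratios taken to run the same way. All 6 genes of the leucine breakdown and flavoprotein list stood higher in sorbitol adjusted over the list alone, and 4 did so over all genes. Their median was 2.08 (camera adjusted p = 1.26e-09), and this list also passed with an estimated correlation (adjusted p = 0.0298). With the sorbitol ratios turned, its median was 1.39 (camera adjusted p = 0.000246, and adjusted p = 0.129 with an estimated correlation). IVD was higher by 2.96 (SE 0.39, adjusted p = 0.00536) and ETF-QO (LOC4349116), which hands electrons of the flavoprotein to the respiratory chain, by 2.63 (SE 0.35, adjusted p = 0.00534). HXK6 was higher by 2.80 (SE 0.32, adjusted p = 0.00289) and the actin gene actin-6 (LOC4337330) by 2.65 (SE 0.32, adjusted p = 0.00408). These 4 genes passed without any single array, and all but ETF-QO (0.56, adjusted p = 0.402) passed with the sorbitol ratios turned. DNA replication genes stood lower in sorbitol, with a median of -0.52 over 24 genes, none of them called over all genes or over the list alone (camera adjusted p = 0.0279, and adjusted p = 0.716 with an estimated correlation). That call was lost without 12 h replicate 1 or 2 (adjusted p up to 0.219), after scaling (0.118) and with quantile normalization (0.129). With the sorbitol ratios turned, the DNA replication median was -0.68 (camera adjusted p = 0.00501). Further lists then passed, among them dehydrins (2.16, camera adjusted p = 0.000246) and ribosomal proteins (-0.66, camera adjusted p = 0.00028). No list passed with the ratios turned and an estimated correlation.

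SWEET1B and RAmy3E were higher in sorbitol than in sucrose by 4.72 (SE 0.87, adjusted p = 0.0225) and 3.21 (SE 0.64, adjusted p = 0.0305), and CCR1 was lower, at -3.07 (SE 0.59, adjusted p = 0.0256). These 3 calls were lost without 12 h replicate 1 or 3 or any sorbitol replicate, with adjusted p-values of up to 0.122, 0.142 and 0.139. That of CCR1 was also lost after scaling (adjusted p = 0.0601), and those of RAmy3E and CCR1 without the arrays numbered 3 (adjusted p = 0.0718 and 0.0503). With the sorbitol ratios turned, that of SWEET1B was lost (3.17, adjusted p = 0.0625). In all, limma called 266 of 18260 features, 183 higher and 83 lower in sorbitol, all at least 2-fold (2613 at an unadjusted p under 0.05). The 2 groups of 3 arrays did not overlap for 30.7% of features. The 10% that chance gives with exchangeable arrays is no measure here, since the sorbitol arrays varied less than the others. With the sorbitol ratios turned, 748 features were called (437 higher and 311 lower), 141 of the 266 kept their call in the same direction, and 35.9% did not overlap, so neither count nor share speaks for a direction. The count was 59 and 60 without 12 h replicate 1 or 3, and 24, 23 and 24 without sorbitol replicate 1, 2 or 3. It was 1367 with the arrays scaled, 2146 with quantile normalization (1191 higher and 955 lower), 1741 with array weights, 851 with only these 6 arrays and 611 without the arrays numbered 3. Here too, scaling and quantile normalization widen the sorbitol ratios by construction.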

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

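The tests of a batch shared by the arrays numbered 3, of RNA of a later time, of wider arrays at 48 h, and the fits without those arrays or without the sorbitol arrays, were chosen only after the results they bear on were seen. For 2 tests written before, a condition was changed after the values were seen. For the size of changes at 48 h, a single pair below 0 had counted against it, and this was replaced by a pair below 0 by more than the SD of the pairs. For dye bias, correlations after scaling were added to the condition, and the reading stayed as it was.

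The first pattern is that ratios against sorbitol were small and yet repeated between the 3 arrays. Probe dye bias of equal size on all arrays was argued against as the whole of it. Such bias cancels between 48 and 24 h, and the mean sorbitol ratio still correlated with that difference at 0.206 over features (0.241, 0.178 and 0.161 for the single arrays). The correlation was 0.141 after scaling (0.173, 0.11 and 0.108), and 0.101, 0.083 and 0.175 with single pairs of 48 and 24 h arrays. Dye bias that varied in size between arrays would not cancel, so these values cannot exclude it. Loss of osmotic strength as the account of the whole 12 h response was argued against, since over 1620 features called at 24 h the median ratio against sorbitol was only 0.155 of the median 12 h ratio against sucrose (0.16 against 1.05, and shares of 0.135, 0.145 and 0.171 by array). The medians went with starved cells being slightly further along the same response than cells in sorbitol. In the 24 h direction they were 0.14, 0.15 and 0.18 on the 3 arrays, where features not called at 24 h gave 0.06. Single genes went both ways. Against sorbitol, SWEET1B (-0.78) and RAmy3E (-0.28) lay opposite to their rise against sucrose, while RAB16B (1.12) lay along it. The leucine breakdown list had a larger median for sorbitol over sucrose (2.08) than at 12 h against sucrose (1.66). The reading therefore covers the median of these features and not every gene. It rests on dye labels alone for the direction of the sorbitol ratios, since with the ratio turned these medians would change sign. A partial contribution of dye bias or of osmotic strength stays open. The shares also rest on the sorbitol columns being natural logs like the others, which their values did not show.

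The second pattern is that replicate 3 stood apart from replicates 1 and 2 at 12 and 24 h. It correlated with them at no more than 0.35 and 0.392, where they correlated at 0.649 and 0.692. At 48 h it did not stand apart, with 0.604 and 0.645 against 0.63. Deviations from the group means correlated at 0.426 or more in each of the 3 pairs of arrays numbered 3, which only describes these arrays and is no test of a shared batch. Nor was it particular to number 3, since replicates 1 and 2 of 24 and 48 h gave 0.565 and 0.442. For RNA of a later time on 12 h replicate 3, the highest correlation with replicates 1 and 2 of 24 and 48 h was 0.337, but with replicates 1 and 2 of its own time it was no higher than 0.35, so this value excludes nothing. With replicate 3 of 24 and 48 h it correlated at 0.591 and 0.522. A shared batch and RNA of a later time cannot be told apart from these values, and no biological explanation was tested.

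The third pattern is that 48 h had 2.64 times as many calls as 24 h while no gene was called for the difference. Wider log ratios on single 48 h arrays may account for part of it, since the ratio of counts was 1.39 after scaling, 1.49 after quantile normalization, and 1.58, 0.70 and 2.31 without 48 h replicate 1, 2 or 3. It was 1.48 without the arrays numbered 3. The 24 h arrays and weighting mattered as well. Without 24 h replicate 1, 2 or 3 there were 3996, 4558 and 4791 calls at 48 h against 670, 515 and 2641 at 24 h. With array weights there were 2700 against 6283. Larger changes at 48 h in the genes that respond stay open as well: over features called at 12 h, the median 48 minus 24 h difference, turned to the direction of the 12 h change, was 0.26, 0.36 and -0.12 in the 3 pairs (SD 0.25), and -0.03 after scaling. The arrays were too few to tell these apart.

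The differences between time points stood out as tested differences of the response to the same treatment. LOC4332932 differed between 48 and 12 h by -2.78 (adjusted p = 0.0343), a call lost without any single array other than 12 h replicate 3 or 24 h replicate 2 or 3, and with quantile normalization (adjusted p = 0.0634). From 12 to 24 h, the chitinase list differed by a median of 0.46 (adjusted p = 0.0331, and adjusted p = 0.818 with an estimated correlation) and the cystatin list by 0.46 (adjusted p = 0.0331, and adjusted p = 0.934 with an estimated correlation). The first was lost without 12 h replicate 3, 24 h replicate 2 or 24 h replicate 3 (adjusted p up to 0.286), and the second without these or 12 h replicate 2 (up to 0.493). Without the arrays numbered 3, the adjusted p-values were 0.289 and 0.197.

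From 24 to 48 h, glycolysis differed by -0.84, ribosomal proteins by -0.53 (adjusted p = 4.35e-05, and adjusted p = 0.964 with an estimated correlation), cyclins by -0.42 (adjusted p = 0.0292, and adjusted p = 0.964 with an estimated correlation), dehydrins by 0.43 and metallothioneins by 0.44 (adjusted p = 0.0342, and adjusted p = 0.613 with an estimated correlation). Without 24 h replicate 3 or 48 h replicate 2 the ribosomal, cyclin, dehydrin and metallothionein calls were lost, that of cyclins also without 48 h replicate 1 and those of dehydrins and metallothioneins also without 48 h replicate 3. Adjusted p-values rose up to 0.37, 0.907, 0.714 and 0.37 in that order, and without 48 h replicate 2 the dehydrin median turned to -0.14. After scaling, the cyclin, dehydrin and metallothionein differences did not pass (adjusted p = 0.156, 0.546 and 0.15), nor after quantile normalization (0.202, 0.489 and 0.202). Without the arrays numbered 3, the dehydrin and metallothionein differences had adjusted p-values of 0.472 and 0.557.

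From 12 to 48 h, glycolysis differed by -1.32, metallothioneins by 0.99, cystatins by 1.17 (adjusted p = 0.024, and adjusted p = 0.886 with an estimated correlation), chitinases by 0.58 (adjusted p = 0.00904, and adjusted p = 0.447 with an estimated correlation) and dehydrins by 0.50 (adjusted p = 0.024, and adjusted p = 0.479 with an estimated correlation). Chlorophyll synthesis differed by -0.39 (adjusted p = 0.0232, and adjusted p = 0.273 with an estimated correlation). Cyclins differed by -0.48, DNA replication by -0.45 and ribosomal proteins by -0.48 (adjusted p = 0.024, 0.0274 and 0.012, and adjusted p = 0.886 for each with an estimated correlation). Without 48 h replicate 2 all of these but glycolysis, metallothioneins and chlorophyll synthesis were lost, and without 12 h replicate 2 or 3 all but glycolysis, metallothioneins and chitinases. Dehydrins, cystatins and chlorophyll synthesis were lost without 48 h replicate 3, and cyclins without 48 h replicate 1. The highest adjusted p-values were 0.226 for cystatins, 0.127 for chitinases, 0.282 for dehydrins, 0.0641 for chlorophyll synthesis, 0.807 for cyclins, 0.814 for DNA replication and 0.705 for ribosomal proteins. After scaling, dehydrins, cyclins and DNA replication did not pass (adjusted p = 0.138, 0.109 and 0.136), nor after quantile normalization (0.56, 0.17 and 0.256), which also ended the ribosomal call (0.101). Without the arrays numbered 3, cystatins, dehydrins, DNA replication and chlorophyll synthesis did not pass (adjusted p = 0.192, 0.147, 0.0929 and 0.075).

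With 3 arrays against 3, the 10 splits of the 6 arrays are too few for a share under 0.05. For sorbitol over sucrose the real split called 266 features and the highest of the others 0, so 1 split called as many. For 24 minus 12 h the real split called 0 and the highest other 0, and all 10 called as many. For 48 minus 12 h the real split called 1 and the highest other 1, and 2 called as many. For 48 minus 24 h the real split called 0 and the highest other 179, and all 10 called as many. That split set 24 h replicates 1 and 2 with 48 h replicate 1 against the remaining 3 arrays, which points to a structure of the samples that does not follow the time points. The real split parts all 3 pairs of same-numbered arrays, as 3 of the others do, and those called 1, 0 and 0. The split with 179 calls parts 1 pair, as do the remaining 5, which called at most 1.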

How the results depend on the processing

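The fits without the sorbitol arrays, without the arrays numbered 3 at 12, 24 and 48 h, with the sorbitol ratios turned, and with a block within the 24 and 48 h arrays alone, and the lists by symbol, were chosen only after the data were seen. As reported, 1660, 1634 and 4307 features were called at 12, 24 and 48 h, 10 against sorbitol, 266 for sorbitol over sucrose, 0, 0 and 1 for 24 minus 12 h, 48 minus 24 h and 48 minus 12 h, and 831 at all 3 times in 1 direction. Word lists gave 2 shifts and lists by symbol 61. Counts given here differed from these by over 1.5 times, and under all alternatives the counts not given stayed within that range. Median centring, a robust prior and both other rules for missing values moved none that far. With the arrays centred and scaled, 2815 were called against sorbitol, 1367 for sorbitol over sucrose and 2 for 48 minus 12 h. With quantile normalization, 3871 and 2146 were called against sorbitol and for sorbitol over sucrose. Both settings give all arrays a like spread, which widens the sorbitol ratios by construction. With single probes as features, word lists gave 8 shifts, by construction over more members. With only the arrays compared, the calls were 815, 368 and 890 at 12, 24 and 48 h, 6979 against sorbitol, 851 for sorbitol over sucrose, 0 for 48 minus 12 h and 225 at all times. That fit drops the spread shared with other groups, which is narrower on the sorbitol arrays. With array weights, 6283 and 2700 were called at 24 and 48 h, 7955 against sorbitol, 1741 for sorbitol over sucrose and 6 for 48 minus 12 h, and word lists gave 4 shifts. With a 2-fold threshold, 1057 and 2627 passed both limits at 12 and 48 h. At an adjusted p under 0.01, the calls were 512, 587 and 1861 at the 3 times, 1 against sorbitol, 29 for sorbitol over sucrose, 0 for 48 minus 12 h and 305 at all times, with 1 shift of word lists and 32 of lists by symbol. With the features of smallest ratios left out, 48 minus 12 h had 5. With an estimated correlation, word lists gave 1 shift, the pathogenesis-related proteins at 24 h, and lists by symbol 1, leucine breakdown for sorbitol over sucrose. Without the sorbitol arrays, the calls were 599, 679 and 2600 at the 3 times, 0 for 48 minus 12 h and 361 at all times. Without the arrays numbered 3, they were 2760 and 3944 at 12 and 24 h, 0 against sorbitol, 611 for sorbitol over sucrose, 36 for 48 minus 12 h and 1532 at all times, and word lists gave 1 shift. With the sorbitol ratios turned, which makes the difference a sum, sorbitol over sucrose had 748. Except where the construction of an alternative is given, the cause was not tested.

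When each array was left out in turn, the calls ran from 382 to 2096 at 12 h, from 515 to 2641 at 24 h, from 1503 to 4791 at 48 h, from 0 to 22 against sorbitol and from 23 to 385 for sorbitol over sucrose. They ran from 0 to 0 for 24 minus 12 h and for 48 minus 24 h, from 0 to 23 for 48 minus 12 h, and from 311 to 931 at all times. Shifts ran from 1 to 4 for word lists and from 48 to 63 for lists by symbol. A group left with 2 arrays took its spread from the shared estimate. RAmy3A at 12 h, which did not pass as reported (0.62), changed sign without 12 h replicate 2 (-0.07, adjusted p = 0.971) and reached 1.21 without 12 h replicate 3, and the cause was not tested. Of 6960 values of named genes under the alternatives, 6075 kept their direction and their side of the threshold, 865 fell below it, 16 passed it, and 4 changed sign. Of these, 3 were for sorbitol over sucrose with the sorbitol ratios turned: ETR4 at 0.92 (adjusted p = 0.213), Os3bglu7 at -0.11 (adjusted p = 0.909) and JAZ13 at 1.59 (adjusted p = 0.0217), against -1.96, 2.31 and -1.65 as reported. With signal intensities not used here, how far dim probes limit these values is unknown.

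With the replicate number as a block over all arrays, the calls were 2014, 2435 and 4929 at 12, 24 and 48 h, 9 against sorbitol, 377 for sorbitol over sucrose, 0, 0 and 4 for 24 minus 12 h, 48 minus 24 h and 48 minus 12 h, and 1154 at all times, with 2 shifts of word lists and 69 of lists by symbol. For 48 minus 24 h, where the numbers pair the arrays, the block within these 6 arrays alone called 1 gene and added 2 list shifts, DNA replication and JAZ. It kept the dehydrin call (camera adjusted p = 0.0301). Of the list shifts by symbol called without it, the block over all arrays ended only that of dehydrins for 48 minus 24 h (camera adjusted p = 0.0534). It added other list shifts. Calls of features changed as well. At 12 h, 1593 of the 1660 features called without the block kept the call. Of 268 values of named genes, 5 fell below the threshold with this block and 3 passed it. The numbers of the 12 h arrays did not meet the condition for pairs: the deviations of replicates 1, 2 and 3 correlated at -0.192, -0.033 and 0.426 with those of 24 h and at -0.094, -0.118 and 0.461 with those of 48 h, so only replicate 3 correlated best with its own number. Replicate 1 at 12 h correlated best with replicate 2 of 24 and 48 h, at 0.38 and 0.373, and replicate 2 with replicate 1, at 0.508 and 0.334, a hint from the data and not the design that numbers 1 and 2 are exchanged at 12 h. No exchanged fit was run, so block results that involve 12 h rest on the numbers as labelled.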

Other observations

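At 48 h, several gene families held members that moved in opposite directions. The trehalose phosphatase gene TPP2, whose enzyme removes the phosphate of the sugar signal trehalose 6-phosphate, averaged 1.79 ± 0.78 (SD, n = 3, limma adjusted p = 0.0013), while TPP1 averaged -1.90 ± 0.63 (adjusted p = 0.0013). Of 5 measured genes of this family 1 rose and 1 fell, also when adjusted over the list alone, with a median of 1.05 (camera adjusted p = 0.795). Of 20 genes of phosphate and nitrogen supply, 4 rose and 5 fell, also when adjusted over the list alone. SPX2 and SPX3, which encode proteins that sense phosphate state, were among the falls, at -2.97 ± 0.43 (adjusted p = 0.000396) and -2.71 ± 0.70 (adjusted p = 8.33e-05). That list did not pass, with a positive median of 0.09 and a test pointing downward (camera adjusted p = 0.72).

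Single genes of sugar and abscisic acid signalling rose at 48 h, while their lists did not pass. The SnRK1 kinase gene SNRK1B averaged 2.04 ± 1.01 (adjusted p = 0.000745) and MYBS1, encoding a regulator of sugar-responsive amylase genes, 1.79 ± 0.72 (adjusted p = 0.00275). Of the 6 measured genes of that list 2 rose, and 2 rose and 1 fell when adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.512). The transcription factor gene BZIP23 averaged 2.03 ± 0.82 (adjusted p = 0.000791), and SAPK6 2.25 ± 0.18 (adjusted p = 0.000193). Of 13 abscisic acid and SAPK genes 3 rose and 4 fell, and 5 rose and 4 fell when adjusted over the list alone, so that list went both ways as well (median 0.38, camera adjusted p = 0.72). The allantoate amidohydrolase gene AAH, of purine breakdown, fell, at -2.49 ± 0.24 (adjusted p = 0.000509), and the auxin response factor gene ARF3 at -2.26 ± 0.32 (adjusted p = 7.11e-05). All genes named in these paragraphs as risen or fallen kept the call without any single array.

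Photosynthesis genes shifted upward at 12 h in these suspension cells, with 4 of 10 risen, 5 when adjusted over the list alone, and a median of 0.62 (camera adjusted p = 0.012, and adjusted p = 0.412 with an estimated correlation). The call was lost without 12 h replicate 1 or 2, with adjusted p up to 0.112. At 24 h 3 of 10 rose, also when adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.0111, and adjusted p = 0.327 with an estimated correlation), and the call was lost without 24 h replicate 1 (adjusted p = 0.0817). PSAH, encoding a subunit of photosystem I, averaged 2.89 ± 1.54 at 48 h, when the list did not pass (median 0.30, adjusted p = 0.102).

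Lists of protein turnover and folding did not pass at any time. The 14 proteasome genes had medians of 0.00, -0.19 and -0.21 at 12, 24 and 48 h (camera adjusted p = 0.877, 0.175 and 0.27), and 16 heat shock protein genes had medians of 0.01, 0.19 and 0.04 (adjusted p = 0.877, 0.69 and 0.988). The autophagy gene ATG8A did not pass either, with ratios of -0.32, -0.23 and -0.20 (adjusted p = 0.299, 0.454 and 0.459). The autophagy list had too few measured members for the test, and 1 of 4 rose at each time, also when adjusted over the list alone. This was ATG8C, at 0.96, 0.83 and 0.76, and its calls were lost without several single arrays, among them replicate 1 of the same time, with adjusted p up to 0.155, 0.208 and 0.302. The isocitrate lyase gene ICL of the glyoxylate cycle averaged 3.39 ± 2.44 at 48 h (adjusted p = 0.00558), a call lost without 48 h replicate 1 or 2 (adjusted p up to 0.0753).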
